A study of Mus musculus with 16 samples.

How the data were processed

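Gene expression was measured on Affymetrix mouse arrays in 16 tissue samples from male C57BL/6J mice, the inbred laboratory strain. Per the labels, 8 samples came from liver and 8 from eWAT, the label's name for a white adipose tissue. Within each tissue, 4 samples came from offspring of control fathers (called CT here) and 4 from offspring of obese fathers (called F1 here, after the labels). Obese fathers had eaten a high-fat diet with 45% lipid for 12 weeks, starting at the age of 8 weeks, and were mated with control females, per the labels' protocols. Offspring were sampled at the age of 14 weeks. RNA was extracted from frozen tissue with a column kit and DNase, and 150 ng of it was amplified and labelled for the array, per the labels' protocols. The sample labels number the 4 samples of a group as biological replicates. Fathers, litters and cages are not given in the sources used here, so p-values measure the spread between these samples, and samples that share a father or litter were counted as separate.

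The deposited value table holds log2 expression values, which the authors made with the RMA method in Transcriptome Analysis Console 4.0, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of each probe set. The values were checked before any test was run. They were written with 2 decimals and ran from 1.47 to 19.93 over 22206 probe sets. The largest gap between the sorted values of 2 libraries was 0.2 within liver and 0.53 within eWAT. Between a liver and an eWAT library it was 1.39 to 1.71, which is what a separate normalization of each tissue would leave. Library medians were 5.21 to 5.24 in liver and 6.34 to 6.56 in eWAT. From 33 to 36 probe sets per liver library and 5 to 7 per eWAT library had a value of 19.9 or more, near the top of the scale, where differences are compressed. Arrays have no read depth, so precision is limited by the number of arrays and by the brightness of each probe set. No scan date or hybridization batch was used here.

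Probe sets were named through the platform's annotation table. Of the 22206 probe sets, 19572 had 1 gene symbol, 0 had several and 2634 had none. The symbols were looked up by gene number in a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. The 19572 named probe sets covered 19505 symbols, and for the 55 symbols with more than 1 probe set the brightest on average was kept. No coordinates were used, because the sources used here name no genome build for the probe sets.

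The comparisons, tests, gene lists, rule for named genes and main alternatives were fixed before the data were examined. In each tissue F1 was compared with CT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, 8 libraries per fit). Genes whose mean lay below the 25th percentile of the libraries in the fit were left out as dim. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. All adjusted p-values given for single genes are from limma. The difference between the F1 effect in liver and that in eWAT was tested as an interaction in 1 fit of 16 libraries. Liver was compared with eWAT within the CT offspring. Because the tissues appeared to be normalized separately, levels were set against each other across tissues only in that comparison and as checks of foreign transcripts. Differences are F1 minus CT, or liver minus eWAT, on the log2 scale, with the standard error (SE) of the fit.

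The 54 gene lists covered metabolic pathways, stress and immune responses, and markers of cell types that the tissues or their neighbours could hold. Of their 1153 entries, 1032 matched a symbol on the array and 121 did not. The matching of older symbols was corrected once after first results had been seen, because 6 entries had been matched to the gene of another symbol. Lists were tested with limma's camera with a preset correlation of 0.01 between genes and adjusted over the 53 lists with 5 or more kept genes. The remaining list was not tested. Camera with a correlation estimated from the data and limma's fry were run as alternatives. Counts "adjusted over the list alone" adjust a list's members only among themselves. A tissue's list p-values compare the list with all other kept genes, and genes of a list are not independent of each other.

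Genes were named by this rule. In each tissue up to 12 called genes per direction were named by smallest p. Where fewer passed, the names were filled up to 12 with the smallest unadjusted p among genes with at least a 1.5-fold difference, given as not passed. Up to 4 kept members of each list described were named by smallest p. For the interaction and the tissue comparison up to 6 genes per direction were named, with the adipocyte, hepatocyte and epididymis lists for the latter. Gene models known only by a number, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were passed over. Transcripts of foreign tissues given by library were taken from those lists or chosen after their values were seen.

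The scripts were tested on simulated data, in which 100 genes per size were changed in values drawn with the spread of each comparison. For liver 45% of genes changed by 1 log2 unit and 75% of those changed by 2 were called, with 3 false among 124 calls. For eWAT the shares were 32% and 84%, with 4 false among 121. For the interaction they were 16% and 79%, with 8 false among 103, and for the tissue comparison 40% and 84%, with 4 false among 130. A list shifted by 0.5 was called in each simulation, with 0 of the 52 other lists. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely. Other splits of the real samples called a median of 4 lists in liver and 11 in eWAT.

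Alternatives changed 1 choice at a time, except that the trend and robust settings of eBayes were changed together. They were no dim-gene filter or one at the 50th percentile, renewed quantile normalization, subtraction of array medians, the replicate number as a block, the same animal as a random block, eBayes with trend and robust settings, array weights, all probe sets, the median of a gene's probe sets, 1 fit over all 16 samples, an adjusted p threshold of 0.1, Spearman in place of Pearson correlation, and leaving out each library in turn. Further alternatives were added after the data were seen, to treat transcripts of other tissues found in some libraries. Other splits of the samples into groups of the same sizes were fitted in the same way.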

Results

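Expression of the whole transcriptome was measured in liver and eWAT of 14-week-old male mice whose fathers had been either control animals or obese after a high-fat diet. Each of the 4 groups (liver CT, liver F1, eWAT CT and eWAT F1) held 4 libraries, named here by group and replicate number. The design asks which genes differ in the offspring of obese fathers in each tissue, whether the difference depends on the tissue, and how the tissues differ in control offspring. Libraries of a tissue correlated at 0.976 to 0.991 over all probe sets, and a liver with an eWAT library at 0.751 to 0.815. The highest share of equal values between 2 libraries of a group was 1.43%, so no library appeared to be a copy of another.

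In liver, Moxd1, Scara5, Fgl1 and Mt2 had the smallest p among the genes that were higher in F1 than in CT. Moxd1, a copper-dependent monooxygenase family member on the fixed list of genes that are higher in male than female liver, rose from 5.98 ± 0.86 in CT to 14.04 ± 0.77 in F1 (mean log2 ± SD, n = 4 each), a 266-fold difference. Scara5, a scavenger receptor that takes up ferritin, rose 12.6-fold, from 5.87 ± 0.34 to 9.53 ± 0.27. Fgl1, a fibrinogen-like protein secreted by hepatocytes, rose 8.54-fold, from 13.60 ± 0.26 to 16.70 ± 0.36. Mt2, a metallothionein that binds zinc and copper, rose 29.4-fold, from 6.84 ± 0.72 to 11.72 ± 0.71. In each of these 4 genes every F1 library lay above every CT library.

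**Figure D1:**
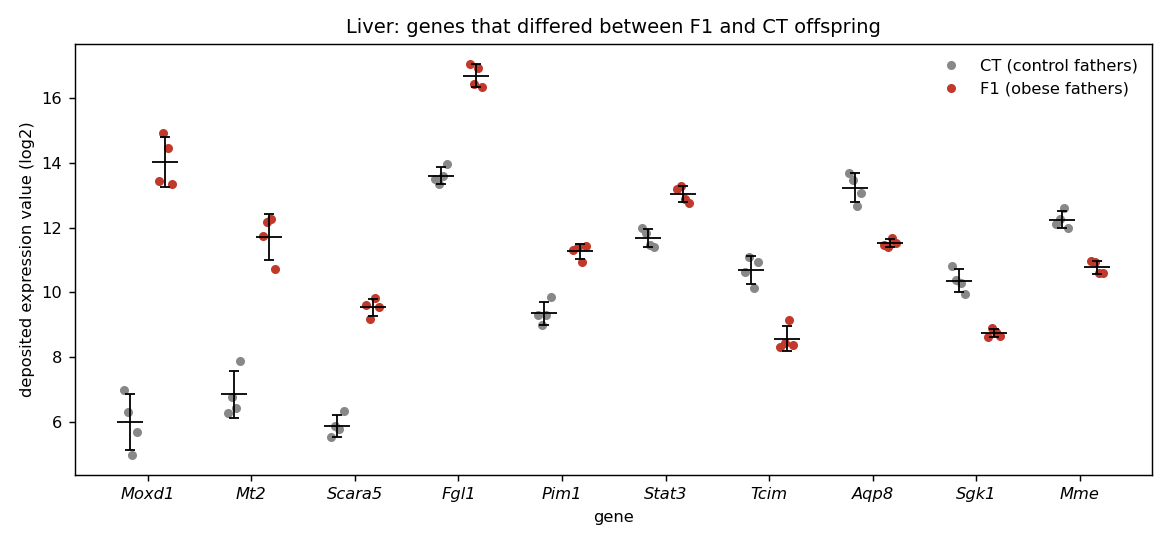
Log2 expression (y axis) of 10 genes called changed in liver, with each of the 4 CT and 4 F1 libraries as a point and the group's mean and SD as a bar. Moxd1 lies at 5.98 in CT and 14.04 in F1, and Sgk1, Tcim, Mme and Aqp8 lie lower in F1 than in CT.

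With limma, 23 of 14723 genes were called changed in liver, 16 higher and 7 lower in F1. The log2 differences were 8.06 ± 0.47 (SE) for Moxd1 and 3.66 ± 0.21 for Scara5 (adjusted p = 6.83e-05 for both), 3.10 ± 0.21 for Fgl1 (adjusted p = 2.36e-04) and 4.88 ± 0.41 for Mt2 (adjusted p = 0.00128). Among mediators of cytokine signalling, the kinase Pim1 rose 3.77-fold (1.92 ± 0.21, adjusted p = 0.0102), and the transcription factor Stat3, which interleukin-6 activates, rose 2.55-fold (1.35 ± 0.19, adjusted p = 0.0335). The interleukin-1 receptor Il1r1 rose by 1.96 ± 0.25 (adjusted p = 0.0187) and the interferon regulatory factor Irf1 by 1.18 ± 0.15 (adjusted p = 0.0152). Cxcl1, a chemokine that attracts neutrophils, rose 5.77-fold, from 5.42 ± 0.46 to 7.94 ± 0.77 (adjusted p = 0.0335). It was the single member called among 14 kept genes of the cytokine and chemokine list, and also when adjusted over the list alone. That list was not called (adjusted p = 0.680), and its median of -0.11 and mean of 0.04 differed in sign. Also higher were the antiproliferative gene Btg2 (1.59 ± 0.18), Fndc3b (1.48 ± 0.20), the amino acid transporter subunit Slc3a1 (1.64 ± 0.23) and Nnmt, which methylates nicotinamide (1.72 ± 0.24).

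The 7 genes that fell in liver of F1 included membrane and signalling proteins. Aqp8, a water channel of hepatocytes, fell by 1.71 on the log2 scale (SE 0.22, adjusted p = 0.0187), from 13.22 ± 0.45 to 11.52 ± 0.12. Sgk1, a kinase that glucocorticoids induce, fell by 1.63 (SE 0.19, adjusted p = 0.0151), and Tcim, a small regulator of transcription, by 2.13 (SE 0.26, adjusted p = 0.0152). Mme, the peptidase neprilysin, fell by 1.48 (adjusted p = 0.0152) and Egln3, an oxygen-dependent prolyl hydroxylase, by 1.80 (adjusted p = 0.0335). The transcription factor Atoh8 fell by 0.90 and the oxysterol-binding protein family member Osbpl8 by 0.94 (adjusted p = 0.0479 for both). The next genes did not pass: the leptin receptor Lepr differed by -1.25 ± 0.20 (adjusted p = 0.0540), Hsd17b11 by -1.12 ± 0.18 (0.0558), the retinol saturase Retsat by -1.33 ± 0.22 (0.0594), Plekhb1 by -1.41 ± 0.23 and the carboxylesterase Ces1g by -1.10 ± 0.18 (both 0.0619). Metallothioneins, serum amyloids, selenium-binding proteins and carboxylesterases have close relatives in the genome, so their single probe sets cannot be attributed to one copy with certainty.

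At an unadjusted p under 0.05, 1347 liver genes (9.15%) differed, against 736.15 by chance, and 677 of them differed at least 1.5-fold, 373 higher and 304 lower. In 792 genes (5.38%) the 4 F1 values lay entirely above or below the 4 CT values, which chance gives for 2.86%. The count of 23 depended on single libraries. It was 7 without CT 2, 10 without CT 3, 8 without CT 4, 10 without F1 2 and 7 without F1 3, and Moxd1, Scara5, Fgl1, Mt2 and Pim1 were the 5 of 21 named calls that held in all 8 such runs.

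Genes of the acute phase, mostly of plasma proteins that the liver makes during inflammation, were higher in liver of F1 as a list. The list also held Mt1, Mt2 and Steap4, which are not plasma proteins. Of 23 kept members 22 had a higher mean in F1, 1 (Mt2) was called over all genes and 15 were called when adjusted over the list alone, with a median difference of 0.85 and a mean of 1.42. The list's median level overlapped between the groups, at 15.16, 14.86, 14.27 and 14.98 in CT 1 to 4 and 15.67, 14.94, 15.75 and 14.19 in F1 1 to 4. The list was called with camera (adjusted p = 1.34e-16) and was the single liver list that stayed called with an estimated correlation (adjusted p = 0.0341 with an estimated correlation). Itih4, a plasma protease inhibitor, differed by 0.94 ± 0.15 (adjusted p = 0.0570), the metallothionein Mt1 by 3.04 ± 0.50 (0.0612) and the metalloreductase Steap4 by 1.21 ± 0.21 (0.0726), so none of these 3 passed over all genes. The serum amyloid genes were uneven within F1. Saa1 reached 14.09 in F1 3 and 13.01 in F1 4, against 5.57 to 7.88 in the other 6 libraries, and Saa2 reached 15.75 and 13.81 against 5.31 to 8.16. Lcn2, an iron-siderophore carrier chosen here after its values were seen, lay at 7.68, 7.33, 11.75 and 12.62 in F1 1 to 4 and at 4.71 to 5.58 in CT. Macrophage markers were not called in liver with camera: their median difference was 0.11 (adjusted p = 0.331), with 16 of 24 members higher and 8 lower. Their median level was 7.22 to 8.00 in the CT libraries and 7.57 to 8.52 in the F1 libraries.

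Several lists of lipid metabolism were also called in liver, in both directions, but each lost its call with an estimated correlation. Genes of fatty acid oxidation and targets of PPARa were lower in 24 of 28 kept members (median -0.46, adjusted p = 1.78e-09, and adjusted p = 0.290 with an estimated correlation). Over all genes 0 members passed with limma, 13 had an unadjusted p under 0.05, and 6 passed when adjusted over the list alone. The peroxisomal thiolase Acaa1b differed by -1.37 ± 0.25 (adjusted p = 0.0833), the fatty acid hydroxylase Cyp4a14 by -4.89 ± 1.04 (0.147), the peroxisomal enzyme Ehhadh by -1.16 ± 0.25 (0.155) and Pdk4, which restrains glucose oxidation, by -1.36 ± 0.30 (0.162). De novo lipogenesis was lower in 11 of 14 members (median -0.44, adjusted p = 7.20e-04, and adjusted p = 0.286 with an estimated correlation), with 5 called when adjusted over the list alone and medians of -0.62 to -0.26 over the alternatives with the preset correlation. The malic enzyme Me1 differed by -1.24 ± 0.24 (adjusted p = 0.108), the elongase Elovl5 by -0.92 ± 0.18 (0.115) and the fatty acid synthase Fasn by -1.36 ± 0.36 (0.255). Triglyceride synthesis and lipid droplet genes were lower in 17 of 21 members (median -0.26, adjusted p = 0.00197, and adjusted p = 0.282 with an estimated correlation), with 0 called by limma alone or over all genes and 4 at an unadjusted p under 0.05. The droplet coat gene Plin4 differed by -1.03 and the glycerol-3-phosphate dehydrogenase Gpd1 by -0.49. Cholesterol synthesis genes were higher in 16 of 19 members (median 0.36, adjusted p = 4.51e-06, and adjusted p = 0.366 with an estimated correlation), with 7 called when adjusted over the list alone. Idi1 differed by 1.23 ± 0.32, Mvk by 0.93 ± 0.24, Nsdhl by 0.82 ± 0.20 and Fdps by 0.73 ± 0.18, all enzymes of the pathway that did not pass over all genes (adjusted p = 0.251, 0.241, 0.224 and 0.218). Peroxisome biogenesis genes were lower in 13 of 14 members (median -0.25, adjusted p = 0.00878, and adjusted p = 0.271 with an estimated correlation). That call ended without CT 3 (adjusted p = 0.0649).

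The remaining liver lists that camera called lost their calls with an estimated correlation too. Genes that are higher in male liver had a median difference of 0.16 but a mean of 0.71 over 18 members, 10 of them higher (adjusted p = 0.00413, and adjusted p = 0.478 with an estimated correlation). Moxd1 and Selenbp2 were the 2 members called, Selenbp2 at 2.44 ± 0.36 (adjusted p = 0.0335), while the complement gene C6 differed by 1.22 ± 0.21 (adjusted p = 0.0670). Adjusted over the list alone 6 members were called, 5 higher and 1 lower. Interferon-stimulated genes were higher in 24 of 25 members by a small amount (median 0.22, adjusted p = 0.00426, and adjusted p = 0.238 with an estimated correlation). Isg15, a ubiquitin-like protein, differed by 0.64 ± 0.28, with F1 2 at 6.31 and the other F1 libraries at 5.56 to 5.63, and by 0.42 without CT 2. Clock genes were higher in 14 of 19 members (median 0.30, adjusted p = 0.0243, and adjusted p = 0.556 with an estimated correlation), and 4 were called when adjusted over the list alone, 3 higher and 1 lower. The clock repressor Nr1d1 differed by 1.58 ± 0.29 (adjusted p = 0.0966), Per3 by 1.72 ± 0.43 (0.224), Dbp by 2.82 ± 0.83 (0.326) and the activator Npas2 by -1.86 ± 0.54 (0.308). The clock call ended without CT 1 (median 0.23, adjusted p = 0.0962), CT 3 (0.36, 0.0649), F1 3 (0.18, 0.106) or F1 4 (0.43, 0.164), and over the alternatives with the preset correlation its median ranged from 0.18 to 0.57. Bile acid genes were lower in 16 of 21 members (median -0.13, adjusted p = 0.0398, and adjusted p = 0.286 with an estimated correlation). Adjusted over the list alone 3 were called, 2 of them higher. The exporter Abcc3 differed by -0.90 ± 0.17 (adjusted p = 0.0966), the hydroxylases Cyp2c70 by 0.73 ± 0.21 and Cyp7b1 by 1.09 ± 0.31. That call ended without CT 3 (adjusted p = 0.137), CT 4 (0.0776), F1 2 (0.143), F1 3 (0.0784) or F1 4 (0.0771), and the median ranged from -0.26 to -0.12 over the same alternatives.

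Transcripts of neighbouring tissues were present in single liver libraries. The exocrine pancreas list was higher in all 19 kept members (median 1.56, adjusted p = 7.20e-04, and adjusted p = 0.754 with an estimated correlation), and its median level was 10.68 in F1 4 against 3.96 to 4.52 in the other 7 libraries. The amylase gene Amy2a5 stood at 17.69 in F1 4, the carboxypeptidase Cpa1 at 14.60 and the chymotrypsinogen Ctrb1 at 14.24. Without F1 4 the list differed by -0.10 (adjusted p = 0.653), and 24 genes were called in liver, 16 of them among the 23. Skeletal muscle genes were higher in 9 of 11 members (median 0.43, adjusted p = 0.0368, and adjusted p = 0.751 with an estimated correlation), with medians of 4.84 in F1 1 and 4.71 in F1 2 against 3.78 to 3.97 in the other 6 libraries. This call ended without CT 1 (median 0.38, adjusted p = 0.0855), CT 2 (0.44, 0.0532), CT 3 (0.50, 0.108), F1 1 (0.25, 0.403) or F1 2 (0.25, 0.425). In all, 12 of 53 lists were called in liver, 7 higher and 5 lower. With fry, which tests a list's own genes against no difference, 5 were called, and with an estimated correlation 1.

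In eWAT no single gene passed, while lists of mitochondrial and lipid-storage genes were higher and macrophage and imprinted genes lower in F1 when tested with the preset correlation. With an estimated correlation 0 lists were called. The kinase Mapk4 had the smallest p, with 5.16 ± 0.56 in F1 and 3.22 ± 0.22 in CT, a difference of 1.95 ± 0.27 (SE) that did not pass (adjusted p = 0.362). Its CT mean lay below the 25th percentile of the eWAT libraries (3.44 to 3.55), so the difference is a lower bound. Limma called 0 of 14773 genes at an adjusted p under 0.05 and 0 under 0.1. At an unadjusted p under 0.05 it gave 1477 genes, 735 higher and 742 lower, against 738.65 by chance. Of these, 863 differed at least 1.5-fold, 418 higher and 445 lower. In 874 genes (5.92%) the groups did not overlap, against 2.86% by chance. A fit over all 16 samples called 25 eWAT genes, the trend and robust settings 0, and array weights 0. Leaving out CT 4 or F1 4 gave 1 call each.

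The eWAT genes with the smallest unadjusted p at 1.5-fold or more, none of which passed (adjusted p = 0.362 for each), included signalling and lipid-storage genes. Higher in F1 were Angpt4 (1.60 ± 0.25), a ligand of the Tie2 receptor, Nxpe2 (1.84 ± 0.30), Fam13a (1.48 ± 0.25), Fam107a (2.15 ± 0.38), Coa7 (1.25 ± 0.22), the potassium channel Kcnj15 (0.91 ± 0.17) and Fitm2 (0.70 ± 0.14), which takes part in forming lipid droplets. Wdr45 (0.76 ± 0.15), Hint2 (1.11 ± 0.22), Zyg11a (1.65 ± 0.32) and the cell adhesion gene Ncam2 (1.42 ± 0.28) followed. Lower in F1 were Spry4, a feedback inhibitor of receptor tyrosine kinases (-1.49 ± 0.24), Cdc42ep3 (-1.19 ± 0.20), the purine receptor P2ry6 (-1.25 ± 0.23) and Rell1 (-1.04 ± 0.19). Lower too were the blood cell transcription factors Runx1 (-1.12 ± 0.20) and Fli1 (-0.74 ± 0.15), Pstpip1 (-0.91 ± 0.17), Parp8 (-1.10 ± 0.22), Skap2 (-0.76 ± 0.15) and Nsmce2 (-0.75 ± 0.14). The pseudogene Morf4l1-ps1 (-1.23 ± 0.24), whose parent gene is a near copy, and the taste receptor Tas2r105 (-0.92 ± 0.18, a lower bound in size, with F1 near the bottom of the scale) completed them.

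**Figure D2:**
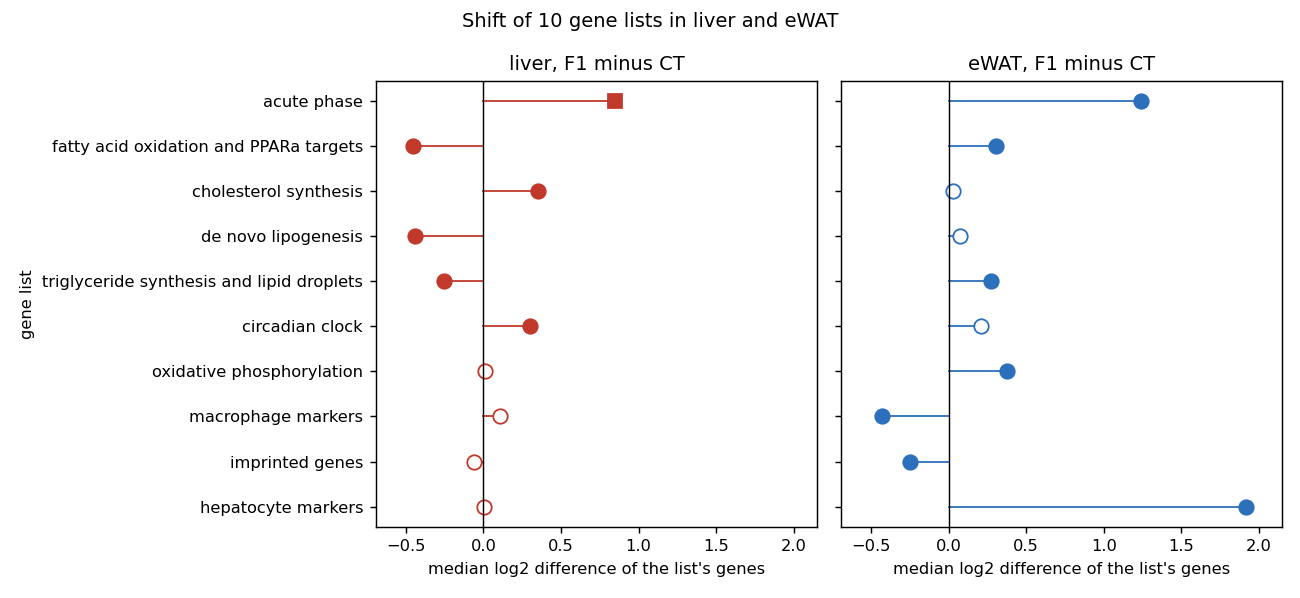
Median log2 difference of F1 minus CT (x axis) for 10 gene lists (y axis) in liver and eWAT. Filled symbols mark lists called by camera with the preset correlation, a square marks the list called also with an estimated correlation, and open symbols were not called; the acute-phase list stands at 0.85 in liver and oxidative phosphorylation at 0.38 in eWAT.

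Oxidative phosphorylation, the respiratory chain and ATP synthase, was higher in eWAT of F1 in 49 of 50 kept members, with a median difference of 0.38 (adjusted p = 1.83e-15, and adjusted p = 0.403 with an estimated correlation). The list's median level was 11.94 to 12.43 in the 4 F1 libraries and 11.45 to 11.71 in the 4 CT libraries. Over all genes, and adjusted over the list alone, limma called 0 members, and 22 had an unadjusted p under 0.05. Cox6c of complex IV differed by 0.76 ± 0.21, Ndufa1 and Ndufb8 of complex I by 0.58 ± 0.16 and 0.59 ± 0.17, and cytochrome c1 (Cyc1) by 0.73 ± 0.22. Triglyceride synthesis and lipid droplet genes were higher in 17 of 20 members (median 0.27, from 0.19 to 0.43 over the alternatives with the preset correlation, adjusted p = 3.24e-04, and adjusted p = 0.237 with an estimated correlation). Adjusted over the list alone 3 were called, and this was the 1 eWAT list that fry called (adjusted p = 0.00835). Besides Fitm2, the droplet coat gene Plin5 differed by 0.83 ± 0.18, and the acyltransferases Gpat4 and Gpat3 by 0.57 ± 0.17 and 0.58 ± 0.20. Fatty acid oxidation genes were higher in 23 of 27 members (median 0.30, adjusted p = 3.24e-04, and adjusted p = 0.403 with an estimated correlation; median 0.18 without both libraries with male tract transcripts, adjusted p = 0.00112), among them Cpt2 of the mitochondrial carnitine shuttle at 0.67 ± 0.20 and the nuclear receptor Ppara at 0.97 ± 0.33. Thermogenic genes were higher in 12 of 16 members (median 0.34, adjusted p = 0.0422, and adjusted p = 0.403 with an estimated correlation), with Cidea at 1.41 ± 0.53 (0.79 without F1 1, the library with seminal vesicle transcripts), Cox8b at 1.11 ± 0.45 and the mitochondrial coactivator Ppargc1a at 0.75 ± 0.33. Ucp1, the uncoupling protein of brown fat, stood at 2.22 ± 0.15 in F1 and 2.38 ± 0.26 in CT, near the bottom of the scale. The thermogenic call ended without CT 1 (adjusted p = 0.107), CT 2 (0.0524), CT 3 (0.0624), F1 1 (0.112) or F1 2 (0.103). It also ended when liver-enriched genes were left out (0.15, adjusted p = 0.125) and without both libraries with male tract transcripts (0.27, 0.0889), and its median ranged from 0.15 to 0.75 over the alternatives.

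Macrophage markers were lower in eWAT of F1 in 22 of 24 members (median -0.43, adjusted p = 7.16e-05, and adjusted p = 0.403 with an estimated correlation). The surface receptor Adgre1, known as F4/80, differed by -1.13 ± 0.35, the lysozyme gene Lyz2 by -0.80 ± 0.28, the chemokine receptor Ccr2 by -0.57 ± 0.18 and the growth factor receptor Csf1r by -0.49 ± 0.16, none passing over all genes (adjusted p = 0.389, 0.412, 0.397 and 0.412). Imprinted genes, expressed from 1 parental copy, were lower in 16 of 20 members (median -0.25, adjusted p = 0.00651, and adjusted p = 0.403 with an estimated correlation). Peg10 differed by -1.85 ± 0.47, Plagl1 by -0.71 ± 0.22, Zim1 by -1.01 ± 0.31 and Rasgrf1 by -0.55 ± 0.17, all without passing. Limma called 0 members of either list, also when adjusted over the list alone, and in each list 6 lower members had an unadjusted p under 0.05. When the libraries eWAT CT 4 and eWAT F1 1, which held transcripts of the male reproductive tract, were both left out, an alternative added after the data were seen, macrophage markers differed by -0.30 (adjusted p = 0.0506, the highest of 23 alternatives with the preset correlation, the lowest 3.66e-07) and imprinted genes by -0.19 (adjusted p = 0.0317). The imprinted call ended in the 4 libraries with more hepatocyte transcripts (adjusted p = 0.119, the highest of the same 23 alternatives, the lowest 6.64e-04), over which the medians ranged from -0.35 to -0.16 for imprinted genes and from -0.62 to -0.30 for macrophage markers.

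Liver transcripts were present in the eWAT libraries at unequal levels. The mean of the hepatocyte markers was 8.86, 7.77, 12.77 and 12.52 in CT 1 to 4 and 10.97, 13.18, 10.68 and 14.03 in F1 1 to 4. Albumin (Alb) ranged from 12.43 to 18.91 in CT and 16.65 to 19.07 in F1. The mean marker level was 12.21 ± 1.65 in F1 and 10.48 ± 2.54 in CT (SD, n = 4 each), a difference of 1.73 (exact permutation p = 0.286, two-sided, 70 relabelings, smallest possible 0.0286). Lists of liver function were also higher in eWAT of F1. They were hepatocyte markers (16 of 16 members, median 1.91, adjusted p = 2.17e-04, and adjusted p = 0.544 with an estimated correlation), male-biased liver genes (18 of 18, 1.10, 4.84e-06, and adjusted p = 0.461 with an estimated correlation) and acute phase (21 of 23, 1.24, 4.11e-05, and adjusted p = 0.403 with an estimated correlation). Xenobiotic metabolism (19 of 19, 0.58, 3.24e-04, and adjusted p = 0.403 with an estimated correlation), bile acid genes (18 of 21, 0.49, 0.0175, and adjusted p = 0.614 with an estimated correlation) and amino acid and urea cycle genes (21 of 24, 0.39, 0.0275, and adjusted p = 0.585 with an estimated correlation) were higher likewise. Adjusted over the list alone, 1 hepatocyte marker and 1 xenobiotic gene were called. With the hepatocyte marker level as a covariate, added after the data were seen, hepatocyte markers cannot differ by much, since the covariate is their own mean. In that fit male-biased genes differed by 0.32 (adjusted p = 0.0981), xenobiotic genes by 0.16 (0.515), bile acid genes by -0.10 (0.549) and amino acid genes by -0.14 (0.442). Oxidative phosphorylation (0.47, adjusted p = 3.22e-19), macrophage markers (-0.48, 1.36e-04), triglyceride synthesis (0.26, 0.00115), imprinted genes (-0.32, 6.64e-04), fatty acid oxidation (0.25, 0.00913) and acute phase (0.36, 0.00117) stayed called in that fit. For acute phase the covariate cannot decide. Liver itself differed between F1 and CT by a median of 0.85 in acute-phase genes and 0.0025 in hepatocyte markers. Liver RNA in eWAT would thus leave an acute-phase excess that the marker level does not take out. A block was also fitted for the 4 libraries with more hepatocyte transcripts against the 4 with fewer. Each side held 2 CT and 2 F1, so the block leaves a gene's difference as it was. Hepatocyte markers (1.91, adjusted p = 1.27e-14), male-biased genes (1.10, 1.27e-14), xenobiotic genes (0.58, 4.85e-07), bile acid genes (0.49, 9.28e-07) and amino acid genes (0.39, 3.26e-05) stayed called with it. The sides were formed from the mean of the hepatocyte markers, so the block takes out much of the spread of liver genes by construction. The smaller adjusted p with the block, 1.27e-14 after 2.17e-04 for hepatocyte markers, is therefore no support for a difference. The acute-phase call in eWAT ended when liver-enriched genes were left out (0.14, adjusted p = 0.101). The hepatocyte marker call ended without CT 2 (median 0.90, adjusted p = 0.0514). The bile acid call ended without CT 1 (0.36, 0.188), CT 2 (0.27, 0.227), F1 2 (0.45, 0.103) or F1 4 (0.19, 0.439), and the amino acid call without CT 1 (0.31, 0.193), CT 2 (0.23, 0.178), F1 2 (0.29, 0.103) or F1 4 (0.28, 0.375). Over all alternatives with the preset correlation the medians of these lists varied widely, with 0.0073 to 3.02 for hepatocyte markers, 0.32 to 1.89 for male-biased genes, 0.14 to 1.57 for acute phase, 0.16 to 0.98 for xenobiotic genes, -0.10 to 0.83 for bile acid genes and -0.14 to 0.70 for amino acid genes.

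**Figure D3:**
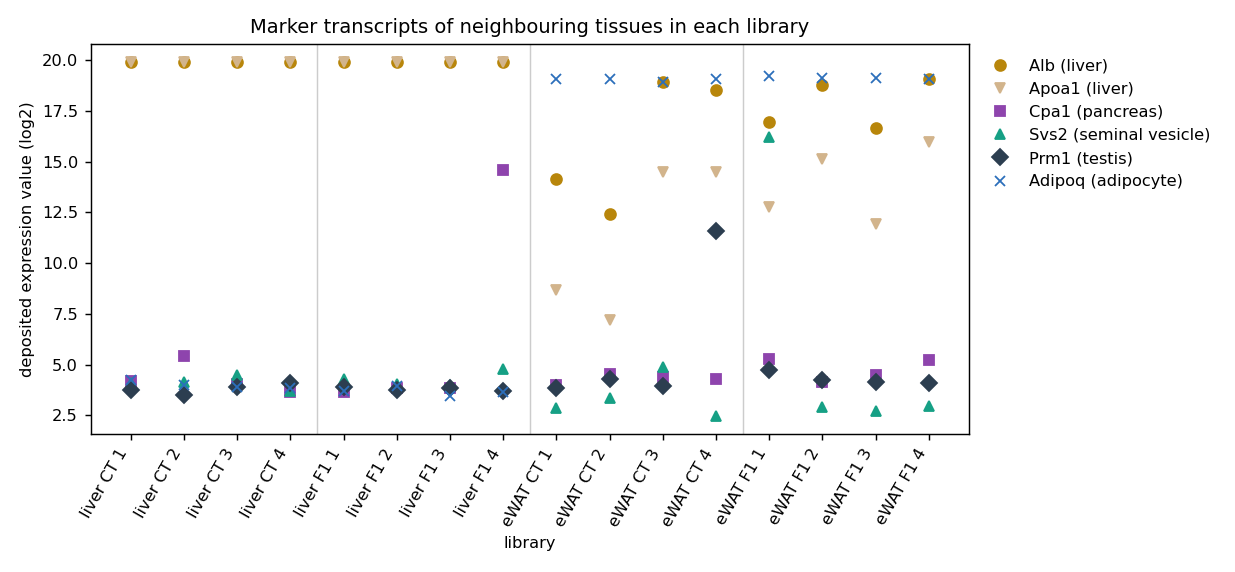
Log2 level (y axis) of 6 transcripts of single tissues in each of the 16 libraries (x axis): Alb and Apoa1 of liver, Cpa1 of pancreas, Svs2 of seminal vesicle, Prm1 of testis and Adipoq of adipocytes. Alb ranges from 12.43 to 19.07 over the eWAT libraries, Svs2 stands at 16.22 in eWAT F1 1, Prm1 at 11.56 in eWAT CT 4 and Cpa1 at 14.60 in liver F1 4.

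Each of the other lists called in eWAT lost its call with an estimated correlation (adjusted p = 0.403 to 0.614). Ribosomal protein genes were higher in 29 of 36 members (median 0.16, adjusted p = 3.24e-04), TCA cycle genes in 16 of 19 (0.16, 0.0365), peroxisome biogenesis genes in 13 of 14 (0.15, 0.0422) and antioxidant genes in 13 of 18 (0.19, 0.0428). Lipolysis genes were higher in 11 of 15 (0.21, 0.0427; 1 called when adjusted over the list alone), interferon-stimulated genes in 18 of 24 (0.30, 0.0351) and mesothelial markers in 9 of 13 (0.49, 0.0422). Lower were extracellular matrix genes in 22 of 26 (-0.21, 0.0275), cell cycle genes in 17 of 23 (-0.24, 0.0365) and skeletal muscle genes in 10 of 13 (-0.49, 0.0275). Without both libraries with male tract transcripts extracellular matrix genes differed by -0.0083 (adjusted p = 0.994), TCA cycle genes by 0.0067 (0.796) and peroxisome biogenesis genes by -0.0033 (0.702), and cell cycle genes (-0.14, 0.516), skeletal muscle genes (-0.38, 0.141), interferon-stimulated genes (0.18, 0.0888), lipolysis genes (0.15, 0.263) and antioxidant genes (0.14, 0.242) lost their calls too. Mesothelial markers differed by 0.08 (adjusted p = 0.702) without CT 2. Over the alternatives with the preset correlation the medians ranged from -0.10 to 0.64 for mesothelial markers, -0.61 to -0.16 for skeletal muscle, -0.39 to -0.02 for cell cycle, -0.31 to -0.0083 for extracellular matrix, 0.15 to 0.34 for interferon-stimulated, 0.0067 to 0.27 for TCA cycle, -0.0033 to 0.27 for peroxisome biogenesis and 0.12 to 0.28 for antioxidant genes. The ribosomal call held in all 8 runs that left out 1 library but ended in the 4 libraries with fewer hepatocyte transcripts (adjusted p = 0.0819), and each of the other 9 calls of this paragraph ended in 3 to 6 of these runs. In all, 22 of 53 lists were called in eWAT, 17 higher and 5 lower, with 14 left when CT 1, CT 2 or F1 1 was left out, 0 with an estimated correlation and 1 with fry.

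The F1 effect differed between the tissues for 12 of 14760 genes, 7 with the larger value in liver and 5 with the larger value in eWAT. The interaction was 6.95 ± 0.65 (SE) for Moxd1 (adjusted p = 1.10e-04), whose F1 difference was 8.06 in liver and 1.11 in eWAT (0.71 without eWAT F1 2). In eWAT Moxd1 lay at 4.78, 6.97, 5.39 and 5.92 in F1 1 to 4 and at 4.56 to 4.81 in CT. It was highest in F1 2 and F1 4, the libraries with the most hepatocyte transcripts, so liver RNA may be part of its eWAT difference. For Mt2 the interaction was 4.28 ± 0.52 (adjusted p = 0.00219) and for Scara5 3.09 ± 0.41 (adjusted p = 0.00400), with F1 differences of 4.88 and 3.66 in liver and 0.60 and 0.57 in eWAT. Spry4 went in opposite directions, with 1.58 in liver and -1.49 in eWAT (interaction 3.07 ± 0.41, adjusted p = 0.00400), although neither difference passed within its tissue. Also larger in liver were Fndc3b (1.72 ± 0.27, adjusted p = 0.0151) and Btg2 (1.61 ± 0.27, adjusted p = 0.0217). Among genes with the lower value in liver, Tcim differed by -2.33 ± 0.33 (adjusted p = 0.00550), Mme by -1.81 ± 0.26 (adjusted p = 0.00802) and H4c3, a histone gene with near-identical copies, by -1.39 ± 0.21 (adjusted p = 0.00881). Mapk4 differed by -2.02 ± 0.32 (adjusted p = 0.0151), with -0.07 in liver and 1.95, a lower bound, in eWAT, and Fam13a by -2.22 ± 0.38 (adjusted p = 0.0235), with -0.74 in liver and 1.48 in eWAT. Egln3 did not pass (-1.82 ± 0.34, adjusted p = 0.0554), but did with the same animal as a random block, which takes equal numbers as animals and called 16 genes, the 12 among them.

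Of the 12 genes 8 were also called within liver, and 11 had the sign of the liver effect. The number of calls was 7 without eWAT CT 3, 25 without eWAT F1 3 and 22 without liver F1 4. Moxd1, Mt2, Scara5, Spry4, Tcim, Mme and H4c3 held in all 16 runs that left out 1 library, while the calls of Btg2 and Fam13a ended in 6 and 9 of them, with adjusted p up to 0.0699. Those of Fndc3b and Mapk4 ended without eWAT CT 3 (adjusted p = 0.0521 for both), and Egln3 passed without liver CT 1 (0.00930) or liver F1 1 (0.0421). A gene left out as dim in a run had no call there.

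Over all 13454 genes kept in both tissues, the F1 differences of liver and eWAT correlated weakly. Pearson's r across genes was 0.0677 and Spearman's rho 0.0275, and 50.4% of genes had the same sign in both tissues. In 100 relabelings of the samples within the tissues, the real one included, 5 gave a Pearson's r as large in absolute size (permutation p = 0.05, two-sided) and 27 a rho as large (permutation p = 0.27, two-sided). Genes are not independent of each other, and r and rho were the 2 measures computed of this 1 relation.

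In CT offspring, liver and eWAT differed by the genes that define each tissue. Adiponectin (Adipoq), an adipocyte hormone, stood at 19.06 ± 0.07 in eWAT and 3.99 ± 0.18 in liver (SD, n = 4 each), a difference of -15.07 ± 0.16 (SE, adjusted p = 2.55e-12). Leptin (Lep, -14.15), Nnat (-13.67), the amine oxidase Aoc3 (-13.50), the amino acid transporter Slc1a5 (-13.41) and Trarg1 (-13.27), which takes part in glucose transporter traffic, followed among the largest differences. Saa4 (12.22 ± 1.18), Aldh8a1 (12.01 ± 0.60), the fatty acid hydroxylase Cyp4a10 (11.90 ± 0.49), Rgn (11.88 ± 1.04), the urea cycle enzyme Cps1 (11.83 ± 1.52) and the hepatocyte transcription factor Hnf4a (11.78 ± 0.80) were highest in liver. Other adipocyte genes were far lower in liver, such as resistin (Retn, -12.99) and perilipin 1 (Plin1, -13.16). In the tissue with the lower value several of these genes lay near the bottom of the scale, such as Adipoq and Lep (3.45) in liver, where the 25th percentile of the libraries was 3.88 to 3.91, so that their differences are lower bounds and their order is uncertain. Of the hepatocyte list, apolipoprotein A1 (Apoa1) differed by 8.72 ± 1.48, and Alb by 3.92 ± 1.24, with liver at the top of the scale, where the difference is compressed. The epididymis and testis list held genes near the bottom of the scale, such as Lcn9 (4.43 in liver and 3.34 in eWAT), and the difference of the testis gene Prm1 did not pass (-2.11 ± 1.46, adjusted p = 0.211).

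Limma called 11097 of 14755 genes between the tissues, 2643 higher in liver and 8454 higher in eWAT, with a median difference of -0.84 over all genes and 519 calls on numbered gene models. This split depends on the scaling, because the tissues appeared to be normalized separately. After renewed quantile normalization 4820 genes were higher in liver and 5094 in eWAT, and after subtraction of array medians 6526 and 4038. The eWAT samples also held liver transcripts, so that the spread of liver genes in eWAT was wide, with SD 3.95 for Cps1 in eWAT CT. Alb stood at 14.16 and 12.43 in eWAT CT 1 and CT 2 but at 18.91 and 18.55 in CT 3 and CT 4. Differences of liver genes between the tissues may therefore be too small, and their order is uncertain.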

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

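The splits of the gene and list counts and the tests of liver RNA, adipocytes, the fathers' group, pancreatic transcripts, leukocytes and sampling time were chosen only after the results they bear on had been seen, as were the alternatives that treat foreign transcripts.

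In 12 of 282 groups of 4 libraries 1 library stood apart from the others, and chance gives about 1 in 20, or 14.1. Among called or named genes in liver, Tcim stood at 9.15 in F1 3 against 8.30 to 8.43, Cxcl1 at 4.73 in CT 4 against 5.57 to 5.69, and Isg15 at 6.31 in F1 2 against 5.56 to 5.63. In eWAT, Coa7 stood at 3.33 in CT 4 against 4.09 to 4.16, and Zyg11a at 4.62 in CT 2 against 5.80 to 6.03 and at 6.67 in F1 3 against 7.32 to 7.43. P2ry6 stood at 9.76 in eWAT F1 4 against 8.99 to 9.05. The median of the macrophage markers was 8.00 in liver CT 2 against 7.22 to 7.34. Transcripts of other organs gave the widest gaps. The exocrine pancreas list stood at 10.68 in liver F1 4 against 3.96 to 4.36 in the other F1 libraries, with Amy2a5 at 17.69 against 6.05 to 6.79. Svs2 stood at 16.22 in eWAT F1 1 against 2.73 to 2.97, beside Svs5 at 14.51 and Svs4 at 14.01, and Prm1 at 11.56 in eWAT CT 4 against 3.86 to 4.31, beside Prm2 at 11.40 and Akap4 at 10.34.

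The F1 difference itself differed between liver and eWAT for 12 genes. The interactions of the named ones were 6.95 for Moxd1, 4.28 for Mt2, 3.09 for Scara5, 3.07 for Spry4, 1.72 for Fndc3b and 1.61 for Btg2, and -2.33 for Tcim, -1.81 for Mme, -1.39 for H4c3, -2.02 for Mapk4 and -2.22 for Fam13a. Chance cannot be excluded for the count, because 6 of 100 splits, the real one included, gave as many and the highest other gave 117. Among these 6 a split with 31 calls was the real grouping with CT and F1 swapped in eWAT. That split therefore held the liver difference itself. When libraries of equal number were relabeled together across the tissues, as if they came from 1 animal, 2 of 35 splits gave as many, and the highest other gave 111. That split parted CT 1, CT 2, F1 1 and F1 3, whose eWAT libraries held fewer hepatocyte transcripts, from the rest, and so many more calls point to a structure of the samples.

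For the count of liver calls the splits argue against chance, at the smallest share that 35 splits can give. Of the 35 splits of the 8 libraries, 1, the real one, gave as many as 23 genes, and the highest other gave 0. The same held for the 677 liver genes with an unadjusted p under 0.05 and a 1.5-fold difference (1 of 35, highest other 419). For the 12 liver lists chance cannot be excluded, since 2 of 35 splits gave as many, and the highest other gave 12. In eWAT all 35 splits gave at least the 0 genes of the real one, and the highest other gave 85. That split parted CT 1, CT 2, F1 1 and F1 3, the libraries with fewer hepatocyte transcripts, from the rest, which points to a structure of the samples. For the 863 eWAT genes with a 1.5-fold difference 1 of 35 splits, the real one, gave as many, and the highest other gave 776. For the 22 eWAT lists it was 1 of 35 too, and the highest other gave 20 and the median other 11. Chance cannot be excluded for these counts, since other splits came close and 0 genes passed. With an estimated correlation 0 of the lists stayed called. For the 11097 genes between the tissues the splits (1 of 35, highest other 0) are no test, because every other split mixed liver and eWAT libraries on each side.

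Liver transcripts reached very different levels in the eWAT libraries, from a mean marker level of 7.77 in CT 2 to 14.03 in F1 4. Liver RNA in the eWAT samples is a candidate explanation, and the values it needs were there: of 300 genes enriched in liver, 99.7% rose with the marker level within groups, against 44.8% of all genes. A lower share of adipocytes, which would raise all other cells alike, is argued against as the whole cause, since 88 markers of other eWAT cells changed by 0.0162 over the range of the marker level (bootstrap interval across genes -0.13 to 0.15) and the liver-enriched genes by 3.33 (2.99 to 3.57), while adipocyte genes changed by -0.18 (-0.30 to -0.08). The fathers' group cannot be told apart from chance as a source, with F1 higher by 1.73 (exact permutation p = 0.286, two-sided), because 4 libraries per group vary too widely. The eWAT lists of liver function may therefore reflect sampling, while oxidative phosphorylation stayed called with the marker level as a covariate (0.47, adjusted p = 3.22e-19, and up to 1.72e-06 over 23 alternatives with the preset correlation) but not with an estimated correlation (adjusted p = 0.403) or with fry (0.138).

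Acute-phase genes were higher in liver of F1, with Saa1 and Saa2 highest in F1 3 and F1 4. The pancreatic transcripts of F1 4 are argued against as the whole cause, since the list differed by 0.74 without that library (adjusted p = 7.46e-15, and up to 9.04e-13 over 17 alternatives with the preset correlation). More leukocytes in the F1 livers cannot be told apart as a cause, because 37 of 64 leukocyte markers lay near the bottom of the scale and the markers went both ways (38 higher, 26 lower, median 0.07). Of the 35 splits 1, the real one, gave a mean shift as large (1.42, highest other 0.98), the smallest share possible. The list had the smallest camera p of the 53 liver lists tested, so this share cannot exclude chance for it. An inflammatory response of the offspring's liver and a shared cage, litter, infection or handling of the F1 animals stay open as hypotheses, since none of these is given in the sources used here.

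Clock genes were called as a list in liver of F1 with the preset correlation but not with an estimated one (adjusted p = 0.556), with higher means of Nr1d1, Per3 and Dbp and a lower mean of Npas2, none of them passing over all genes. A different sampling or feeding time of the groups may account for it: over the 19 clock genes the F1 differences of liver and eWAT correlated (r = 0.586, bootstrap interval 0.17 to 0.84, permutation p = 0.00859 and rho = 0.514 across genes, 15 with the same sign, and r = 0.586 with the marker level as a covariate), although genes are not independent and a shared biological effect would give the same. The pancreatic transcripts of F1 4 cannot be told apart as part of the cause, because without that library the mean shift was 0.810 of its size (interval 0.215 to 0.973; 0.42 after 0.52) while the median rose from 0.30 to 0.43, and the call ended (adjusted p = 0.164, the highest of 17 alternatives with the preset correlation, the lowest 3.75e-04) with 1 library fewer and an SD across the genes of 1.08 after 1.17. Chance cannot be excluded either, with 3 of 35 splits giving a mean absolute shift as large (0.97, highest other 1.08). The fathers' diet stays among the open explanations, as untested.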

How the results depend on the processing

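The alternatives that treat foreign transcripts were chosen only after the data were seen; all other settings were planned. In liver the named genes kept their direction under every alternative run, but calls moved. Counted once for each gene and setting, 25 calls ended and 31 were new outside the runs that leave out 1 library. Within those runs 85 ended and 4 were new. Counted once for each list and setting, calls that ended in the same direction numbered 22 in liver and 110 in eWAT outside those runs, and 15 and 53 within them. Calls that ended with the direction turned numbered 3 more in eWAT outside those runs and 1 more in liver within them. The count of 23 liver genes became 74 with trend and robust settings (22 of the 23 kept), 51 in 1 fit over all samples (20 kept) and 53 at an adjusted p under 0.1. The 12 liver lists became 1 with an estimated correlation and 5 with fry. In eWAT 1 fit over all samples called 25 genes, other settings 0 or, without CT 4 or F1 4, 1. The 863 eWAT genes with a 1.5-fold difference became 559 with the filter at the 50th percentile and 1382 in the 4 libraries with fewer hepatocyte transcripts, where fewer samples were used. The 22 eWAT lists became 13 with that filter, 14 with the hepatocyte covariate, 8 without liver-enriched genes, 14 without both libraries with male tract transcripts, 0 with an estimated correlation and 1 with fry. The 12 interaction genes became 36 with trend and robust settings (all 12 kept). The correlation of the tissues' differences was 0.0677 and Spearman's rho 0.0275. For all of these, and where no construction is named, the cause was not tested.

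Leaving out 1 library gave 7 to 24 liver genes, 699 to 793 with a 1.5-fold difference and 8 to 13 liver lists; 0 to 1 eWAT genes, 762 to 1054 and 14 to 22 eWAT lists; 7 to 25 interaction genes; 10647 to 11114 genes between the tissues; and correlations of 0.0474 to 0.0758. The directions of 4 list tests turned: exocrine pancreas in liver without F1 4 (-0.10, and up to 2.10 when another library was left out), bile acid and amino acid genes in eWAT with the hepatocyte covariate (-0.10 and -0.14) and extracellular matrix in eWAT without both libraries with male tract transcripts (median -0.0083, with the test turned). In eWAT the medians of mesothelial markers (-0.10 in the 4 libraries with more hepatocyte transcripts) and peroxisome genes (-0.0033 without both libraries with male tract transcripts) changed sign while the test did not. With the preset correlation, acute phase, fatty acid oxidation, de novo lipogenesis, cholesterol and triglyceride synthesis, interferon-stimulated and male-biased genes in liver kept their calls under every alternative run, as did oxidative phosphorylation, fatty acid oxidation and triglyceride synthesis in eWAT. In the male-biased liver list 10 members were higher and 8 lower (median 0.16, mean 0.71), and no alternative left out Moxd1. Its call is thus no sign of a shift of the whole list.

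The samples share only their numbers. Deviations of same-numbered CT and F1 libraries correlated at -0.31 to 0.21, so the numbers do not pair them. With the replicate number as a block 6 liver genes were called (5 of the 23), 689 with a 1.5-fold difference and 12 lists. In eWAT the same counts were 0, 918 and 23. With this block 9 interaction genes (8 of the 12) and 10980 genes between the tissues were called. The correlation stayed 0.0677 by construction, because the block leaves each gene's difference as it was. Of the 8 same-numbered pairs of a liver and an eWAT library 6 correlated best with their own number, a hint from the data only. The same-numbered correlations were weak, with r from 0.00997 to 0.0501. Precision is limited by 4 arrays per group, by probe sets at the top of the scale in liver and by dim probe sets, where signal lies near background.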

Other observations

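The test of this part and the choice of what it describes were made only after the results had been seen.

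Several lists with single called genes or with members on both sides were not called in liver of F1. Among 18 kept glucocorticoid targets Mt2 rose and Sgk1 fell by 1.63 on the log2 scale, and 6 were called when adjusted over the list alone, 2 higher and 4 lower. Their median of -0.07 and mean of 0.11 differed in sign (adjusted p = 0.602). Of 21 immediate early genes, which respond within minutes to stimuli, Btg2 was called over all genes, and 8 were called when adjusted over the list alone, 3 higher and 5 lower (median -0.23, adjusted p = 0.645). Of 18 genes of angiogenesis and hypoxia Egln3 was called, while 12 of the 18 had a higher mean (median 0.09, mean -0.03, adjusted p = 0.680). Antioxidant genes were lower in 14 of 17 members without passing (median -0.10, adjusted p = 0.0531), and genes of the unfolded protein response higher in 12 of 19 (median 0.28, adjusted p = 0.0993). Marker lists of B cells (0.14, adjusted p = 0.636), T and NK cells (-0.01, 0.837) and neutrophils (-0.04, 0.645) were not called in liver. The neutrophil list's mean of 0.64 differed in sign from its median.

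In eWAT, genes of adipocyte identity were higher in 18 of 21 members without passing (median 0.12, adjusted p = 0.156), and antigen presentation genes of MHC class II lower in 7 of 9 (median -0.23, adjusted p = 0.0639). Adipose progenitor markers (-0.24, adjusted p = 0.212) and endothelial markers (-0.0013, 0.942) were not called. Fgl1, which rose in liver, lay at 7.05, 8.45, 7.19 and 10.25 in eWAT F1 1 to 4 and at 5.51 to 6.35 in CT, and Saa1 at 2.59, 3.62, 5.23 and 7.07 in F1 and 2.15 to 2.48 in CT. Both genes are made by hepatocytes, whose transcripts these libraries also held.

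A hypothesis is that the liver transcripts in an eWAT sample came from the liver of the same animal, carried over at dissection, and that replicate numbers mark animals across tissues. If so, deviations of liver-enriched genes in an eWAT library should resemble those of the liver library with its number. Over 653 genes the correlations of the real pairing, summed over the 8 libraries, came to 0.582. Each was weak, with r from 0.018 to 0.122. A share of 0.00521 of the 576 possible pairings within groups (3 of 576) reached as large a sum, the highest 0.632. In 5 of 8 libraries the own liver matched best. Carry-over from the same animal may thus account for liver RNA in eWAT, although genes are not independent, the labels do not say that numbers mark animals, and a response shared by both tissues of an animal could give the same.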
